A study of Mus musculus with 12 samples.

How the data were processed

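Expression was measured on arrays in 12 samples of sorted mouse bone cells, 3 in each of 4 groups given by the labels: progenitors and osteoblasts at 5 and at 8 weeks. Biotin-labelled total RNA of untreated C57BL6 mice was used, per the labels. The array platform, the background correction, the normalization, the filter behind the smaller matrix and the genome build are not given in the sources used here. The authors deposited normalized intensity values on a linear scale for 24539 probe sets that are named for Ensembl transcripts. The deposited series value table holds the log2 of these values, with a largest difference of 5e-04 when checked. The authors also deposited limma tables for the 4 pairwise comparisons, with log2 differences and group means, p-values and q-values, whose filter and q-value method are not stated. Another deposited matrix leaves out 823 probe sets, and all 819 of these that have a chromosome in RefSeq are on chromosome X, with 3 probe sets of X kept; its largest log2 difference from the full matrix was 8e-04. A filtered deposited matrix holds 13880 probe sets, with no maximum intensity below 102, and leaves out 2210 probe sets with a higher maximum, of which 503 are on chromosome X.

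The design assumed a log2 matrix, and the log2 was taken because the deposited matrix is linear. No further normalization was applied. Of several probe sets of a gene the one with the highest mean was used, which concerned 5237 genes, and 162 probe sets without a symbol were left out, leaving 16754 genes. Log2 intensities ranged from 3.14 to 13.7 with a median of 7.36. Symbols were matched to RefSeq symbols and synonyms, which succeeded for 16611 genes. Gene positions come from the authors' tables, so genes of chromosome X have none. Array data carry no read depth, and the number of arrays limits the precision.

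Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes, two-sided) in 1 fit of all 12 samples with 4 group means. The fit had 8 residual and 2.44 prior degrees of freedom. The contrasts were osteoblasts against progenitors at each age, 8 against 5 weeks in each cell type, and the difference of the cell type contrast between ages. A gene passed, and is said to have risen or fallen, at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Shared genes were counted by direction beside the number expected from independent calls.

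Gene lists were written by hand, 39 in number with 762 members, of which 714 were measured. They cover osteoblast matrix, osteogenic transcription factors, osteocytes, stromal progenitors, fibroblasts, tendon, adipogenic genes, chondrocytes, pericytes, skeletal muscle, endothelium, granulocytes, macrophages, osteoclasts, erythroid cells, B lymphoid, T and NK cells, megakaryocytes, mast cells, Schwann cells, cell cycle, collagen folding, matrix proteases, the Wnt, BMP and TGF-beta, Notch, hedgehog and IGF pathways, imprinted growth genes, niche factors, inflammatory cytokines, the interferon response, immediate early genes, glycolysis, oxidative phosphorylation, steroid receptors, Y-linked genes, X-linked genes that escape inactivation, and surface proteins of the sort. Each was tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Alternatives were an estimated correlation and fry, which asks whether the genes of a list move one way on balance and does not compare the list with other genes. Of 195 list results, 28 had a median, mean and test that differed in sign, and 0 of these 28 passed by camera. Members were also adjusted over the list alone.

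The named genes of a contrast are the 10 largest rises and the 10 largest falls, or 5 and 5 for the difference between ages, among genes that passed. Replicate ranges of the groups had to be apart (not asked of the difference between ages), the higher group mean had to reach the median of all probe sets, and numbered gene models, microRNAs and small nucleolar RNAs were left out. Up to 4 members with the lowest adjusted p were added per list, with Y-linked genes and X homologues for the sex labels and Ly6a and Itgav for the sort. The groups, contrasts, tests, lists, rule for named genes and first set of alternatives were chosen before the data were examined.

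Those alternatives were the replicate number as a block, the 2 compared groups alone, a filter on genes below the median of all probe sets, the filtered matrix, the matrix without chromosome X, the series value table, quantile normalization, median centring, limma-trend, array quality weights, the probe set with the largest variance, all probe sets, a minimum change of 2-fold, leaving out chromosomes X and Y, and leaving out each library in turn. A block for slide or scan date was not run, because no file gives one. The leukocyte score of a library, the mean of its granulocyte and macrophage genes, was added as a covariate after seeing the data. Leaving out 8-week osteoblast library 1 and 5-week progenitor library 2 was planned among the libraries left out in turn and singled out then. The first stood apart in its residual SD, and the second only in its mean of the Schwann and neural list. The fit was tested on simulated data with the same groups, in which 200 of 16754 genes were changed. It recovered 79% to 81% of 2-fold and 94% to 99% of 4-fold changes in the pairwise contrasts, and 55% and 88% in the difference between ages, with 5 to 12 false calls. The simulated noise was independent between genes, with the same SD of a gene in all libraries. It held no correlated genes and no library that stood apart, so these rates need not hold for the real contrasts. Some genes of the lists and of the named sets are not reported here. The authors' summary sheets were not used, since their counts were recomputed from the tables.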

Results

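Gene expression was measured on arrays in 12 libraries from mouse bone cells that were freshly sorted after collagenase digestion. The labels divide the cells into pre-osteoblastic progenitors and mature osteoblasts, each taken at 5 and at 8 weeks of age, with 3 libraries in each of the 4 groups. Cells were sorted on the lineage markers (Lin), Sca-1, CD51 and CD31, and the labels do not give the gate of each population. The 8-week samples are labelled male and the 5-week samples female, so every comparison between ages is also one between sexes. Nothing says whether the replicates are separate animals or pools, so the p-values measure only the spread between these samples. All values are normalised log2 intensities of 16754 genes, and the number of arrays limits their precision. Gene positions are those of the authors' deposited tables, whose genome build is not named and which hold no gene of chromosome X. Values after ± are standard errors unless they are named as SD, with n = 3 libraries per group. No background level is given, so where the lower mean of a gene that differs is under the lower quartile of the libraries, 5.055 to 5.12, its difference is only a lower bound. Among the genes named further on, this holds for Sp7, Serpina1a, Mog, Slain1, Colec10, Akr1c18, Wnt2 and Sox10 between cell types at 5 weeks, for Panx3, Calml3, Colec10, Krtdap, Wnt2, Cxcl13, Opcml, Ccl8 and Sox10 at 8 weeks, for Clec7a, Tph2, Il7 and Cybb with age in osteoblasts, and for Spock3 and Uty with age in progenitors. The difference between ages of Dusp15 and Sox10 also rests on progenitor means under that quartile.

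The first principal component held 64.9% of the variance and the second 12.8%. Libraries of the same group correlated with r between 0.9853 and 0.994 across genes, which are not independent replicates, and libraries of different groups with r between 0.9325 and 0.9898. The 8-week osteoblast library 1 stood apart, with a residual SD of 0.26 against 0.158 to 0.212 in the others. Its mean log2 intensity over the granulocyte and macrophage lists was 9.8, against 8.14 and 8.1 in the other 8-week osteoblast libraries and 6.61 to 7.63 in the 5-week osteoblast libraries. Ptprc, which encodes the leukocyte antigen CD45, was at 10.99 in that library. The 5-week progenitor library 2 had the highest mean of the Schwann and neural list among progenitors, 7.508, against 7.01 and 6.71 in the other 5-week progenitor libraries.

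**Figure D1:**
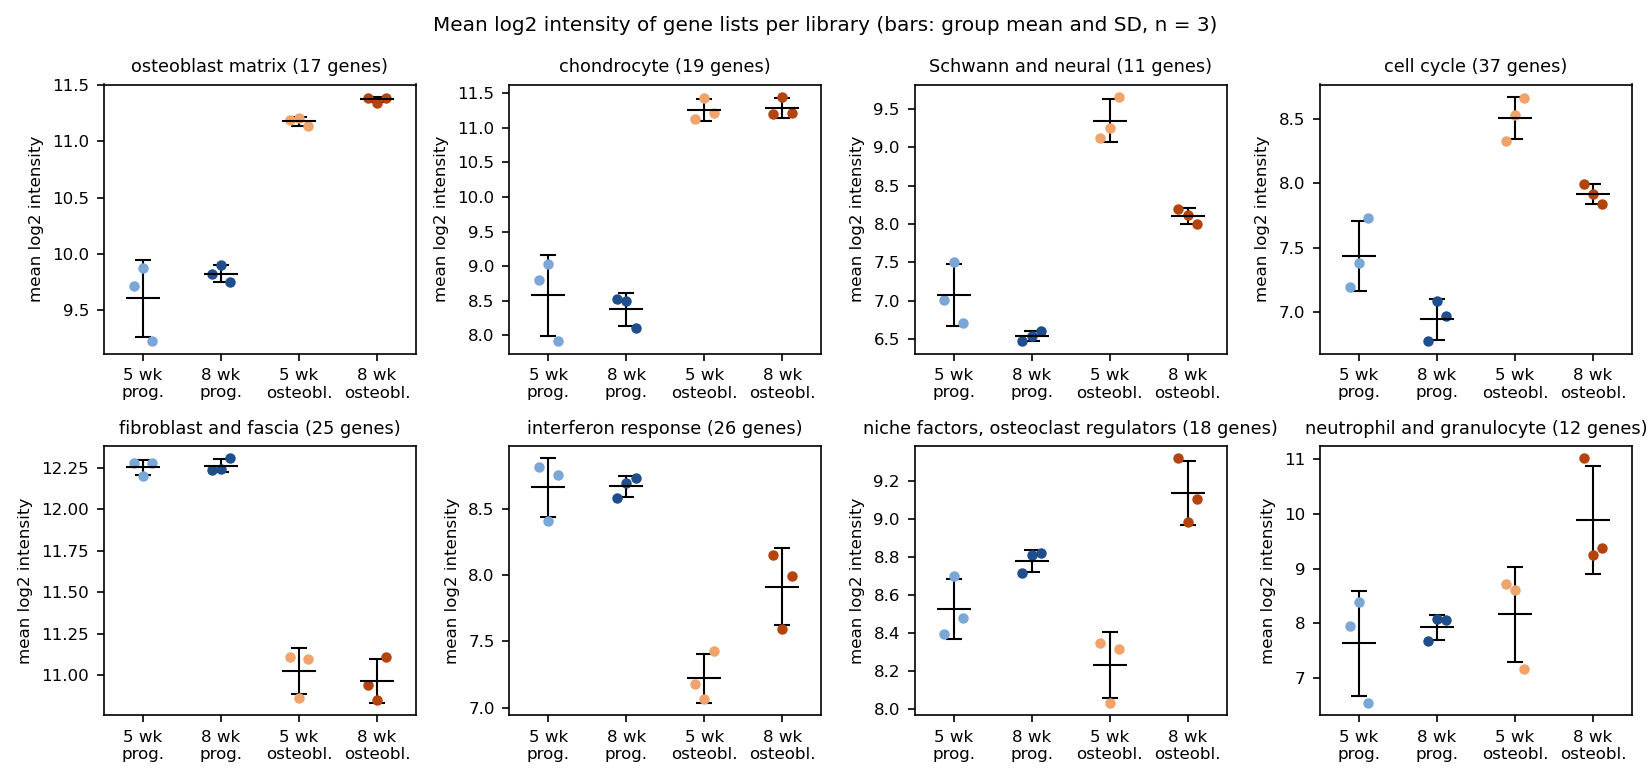
Mean log2 intensity of 8 of the gene lists in each of the 12 libraries, grouped by age and cell type; points are libraries, and bars give the group mean with its SD. The granulocyte list reaches 11.019 in 8-week osteoblast library 1, against 9.25 and 9.386 in the other 8-week osteoblast libraries.

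The comparison of osteoblasts with progenitors at 5 weeks asks which genes separate the populations in the younger animals. Panx3, a channel protein of hypertrophic chondrocytes and osteoblasts, was 59.3-fold higher in osteoblasts, with a log2 difference of 5.89 ± 0.315 (adjusted p = 1.42e-06 by limma). Its mean log2 intensity was 5.52 ± 0.81 (SD) in progenitors and 11.41 ± 0.29 (SD) in osteoblasts, and it lies on chromosome 9 from 37659902 to 37669222. Sp7, the transcription factor osterix that osteoblast differentiation requires, rose by 5.12 ± 0.469 from a progenitor mean of 5.11 (chromosome 15, 102356609 to 102366325). Lgr6, an R-spondin receptor, rose by 5.27 ± 0.309 (38.6-fold; chromosome 1, 134983301 to 135105276), and the bone matrix protein gene Ibsp by 4.72 ± 0.645 (26.3-fold). Krtdap was 36.1-fold lower in osteoblasts, with a log2 difference of -5.17 ± 0.145 (adjusted p = 5.2e-08 by limma; chromosome 7, 30787896 to 30791097). Dpp4, a marker of fascia fibroblasts, differed by -4.52 ± 0.218 (chromosome 2, 62330073 to 62412231), the Wnt ligand gene Wnt2 by -4.36 ± 0.178 (chromosome 6, 17988940 to 18030585) and the angiopoietin receptor gene Tek by -4.89 ± 0.323 (chromosome 4, 94739289 to 94874976). Also among the 10 largest rises were Ptgds, Col9a2, Serpina1a, Mog and Slain1, between 4.71 and 5.84. The other genes with the largest falls were Colec10, AI607873, Ackr1, Prdm8, Akr1c18 and Mgam, between -5.24 and -4.30. Of these Akr1c18 was uneven in progenitors, at 8.72 ± 2.96 (SD), and lost its call in a fit of these 2 groups alone (adjusted p = 0.0622).

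Genes of the skeletal lineages rose in 5-week osteoblasts. Of the 17 measured genes of osteoblast matrix and mineralisation 12 rose, and 13 when adjusted over the list alone (list median 1.25, adjusted p = 1.16e-07 by camera; adjusted p = 0.189 with an estimated correlation). Among them were Alpl, the alkaline phosphatase of mineralising bone, at 3.59 ± 0.308, Omd at 1.53 ± 0.133 and Ifitm5 at 2.34 ± 0.233. Of 14 osteogenic transcription factors 8 rose and 1 fell, the same counts as when adjusted over the list alone (adjusted p = 0.000495 by camera; adjusted p = 0.24 with an estimated correlation). The vitamin D receptor gene Vdr rose by 3.19 ± 0.208, Dlx5 by 2.27 ± 0.2 and Tcf7 by 1.88 ± 0.166. All 19 chondrocyte genes rose, also when adjusted over the list alone (list median 2.75, adjusted p = 5.34e-15 by camera; adjusted p = 0.189 with an estimated correlation). They include Col9a2 at 5.10 ± 0.335, Col10a1, the collagen of hypertrophic cartilage, at 3.75 ± 0.297, Hapln1 at 3.68 ± 0.295 and Pth1r, the parathyroid hormone receptor gene that osteoblasts also express, at 1.47 ± 0.077. The chondrocyte median was larger than the 1.25 of the osteoblast matrix list. Which cells inside the osteoblast gate express the chondrocyte genes was not tested. Of 9 tendon and ligament genes 6 rose, as many as when adjusted over the list alone (adjusted p = 0.000201 by camera; adjusted p = 0.286 with an estimated correlation). Among them were the transcription factor genes Scx at 1.86 ± 0.261 and Mkx at 1.69 ± 0.205. Of 29 genes of collagen folding and secretion 9 rose and 3 fell, with the same counts when adjusted over the list alone (adjusted p = 0.0162 by camera; adjusted p = 0.207 with an estimated correlation). The hydroxylase genes P3h1 and Plod2 rose by 0.72 ± 0.081 and 1.35 ± 0.161, and the procollagen proteinase genes Adamts2 and Bmp1 differed by -1.03 ± 0.096 and -1.08 ± 0.103.

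Markers of other cell types moved too. Of 11 Schwann and neural genes 8 rose in 5-week osteoblasts, and 10 when adjusted over the list alone (list median 1.68, adjusted p = 9.74e-07 by camera; adjusted p = 0.189 with an estimated correlation). Sox10, the transcription factor of neural crest glia, rose by 1.95 ± 0.115. The list mean was 9.127, 9.25 and 9.659 in the osteoblast libraries. Of 13 pericyte and smooth muscle genes 9 rose and 1 fell, and 10 rose and 1 fell when adjusted over the list alone (adjusted p = 2.57e-05 by camera; adjusted p = 0.189 with an estimated correlation). The contractile genes Tagln, Acta2 and Myh11 rose by 2.17 ± 0.144, 1.62 ± 0.126 and 3.30 ± 0.276. Of 13 erythroid genes 2 rose, as many as when adjusted over the list alone (adjusted p = 0.0162 by camera; adjusted p = 0.638 with an estimated correlation). These were Tfrc, the transferrin receptor gene that dividing cells of many kinds express, at 2.99 ± 0.193 and the blood group gene Rhd at 1.51 ± 0.231. The granulocyte list, with a median of 0.69, and the macrophage list, with a median of 0.33, did not pass (adjusted p = 0.364 and 0.174 by camera).

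Proliferation and glycolysis genes rose in 5-week osteoblasts, while fibroblast, inflammatory and interferon genes fell. Of 37 cell cycle genes 32 rose, and 34 when adjusted over the list alone (list median 1.10, adjusted p = 6.19e-15 by camera; adjusted p = 0.189 with an estimated correlation). Among them were the replication licensing genes Mcm3 at 0.89 ± 0.076 and Mcm2 at 1.14 ± 0.111. Of 20 glycolysis and hypoxia genes 11 rose and 2 fell, also when adjusted over the list alone (adjusted p = 3.29e-05 by camera; adjusted p = 0.189 with an estimated correlation). Pfkl, a phosphofructokinase gene, rose by 1.92 ± 0.143, and Adm, the gene of the vasodilator adrenomedullin, differed by -2.25 ± 0.169. Of 29 immediate early and dissociation genes 9 rose, as many as when adjusted over the list alone (list median 0.16, adjusted p = 0.00737 by camera; adjusted p = 0.71 with an estimated correlation); Ier2 rose by 0.88 ± 0.141, and Cyr61 and Ctgf, which encode secreted matrix proteins, by 0.52 ± 0.089 and 0.40 ± 0.076. Of 37 Wnt signalling genes 18 rose and 9 fell, also when adjusted over the list alone (adjusted p = 0.0178 by camera; adjusted p = 0.286 with an estimated correlation), with the antagonist gene Dkk2 at -4.11 ± 0.296 and the receptor gene Fzd4 at -2.09 ± 0.15. Of 25 fibroblast and fascia genes 17 fell and 1 rose, and 18 fell when adjusted over the list alone (adjusted p = 3.42e-07 by camera; adjusted p = 0.189 with an estimated correlation). Clec3b differed by -3.77 ± 0.233 and Fbln2 by -2.63 ± 0.226. Of 27 inflammatory genes 13 fell, and 15 fell and 1 rose when adjusted over the list alone (adjusted p = 4.35e-05 by camera; adjusted p = 0.286 with an estimated correlation); the chemokine genes Ccl7 and Ccl2 differed by -4.13 ± 0.28 and -3.00 ± 0.204. Of 26 interferon response genes 22 fell, and 24 when adjusted over the list alone (adjusted p = 7e-13 by camera; adjusted p = 0.189 with an estimated correlation). Among them were Ifit2 at -1.94 ± 0.13 and Ifit1 at -2.85 ± 0.263. Of 9 surface protein genes of the sort 4 fell, also when adjusted over the list alone (adjusted p = 0.0178 by camera; adjusted p = 0.189 with an estimated correlation). Ly6a, which encodes Sca-1, differed by -2.75 ± 0.133, and Itgav, which encodes CD51, by 0.02 ± 0.059 (adjusted p = 0.825 by limma). The cells were sorted on Sca-1, so the difference of Ly6a and its part in the list call are no finding. The others that fell in this list were Itgb3, Ly6e and Itgb5, none of them a marker used for the sort.

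By limma 4981 genes differed between the populations at 5 weeks, 2419 higher and 2562 lower in osteoblasts, and 1640 by at least 2-fold (931 higher, 709 lower). Without 5-week progenitor library 2, one of the libraries left out in turn, 4545 genes passed. The erythroid list lost its call without 5-week progenitor library 3 (adjusted p = 0.0647) or 5-week osteoblast library 1 (adjusted p = 0.175), the immediate early list without 5-week progenitor library 3 (adjusted p = 0.054), and the Wnt list without 5-week osteoblast library 1 (adjusted p = 0.0642).

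The comparison of osteoblasts with progenitors at 8 weeks asks the same of the older animals. Panx3 was higher in osteoblasts, with a log2 difference of 6.76 ± 0.315 (adjusted p = 5.86e-07 by limma) from a progenitor mean of 4.81. The cartilage collagen gene Col9a2 rose by 5.98 ± 0.335 (63.2-fold; chromosome 4, 121039385 to 121055322), from 5.67 ± 0.47 (SD) to 11.65 ± 0.12 (SD). Adipoq, which encodes the hormone adiponectin, rose by 5.42 ± 0.347 (42.9-fold; chromosome 16, 23146536 to 23158028). Colec10, a collectin gene, was lower in osteoblasts at -5.91 ± 0.294 from a mean of 4.07 there (chromosome 15, 54410774 to 54466358), and Cxcl13, a B cell chemoattractant gene, differed by -4.51 ± 0.199. The other genes with the largest rises were Col11a2, Gdpd2, Col9a3, Calml3, Col10a1, Serpina3g and Ptgds, between 5.05 and 5.66. The other genes with the largest falls were Krtdap, Ackr1, Tek, Cadm3, Lypd2, Prdm8, Wnt2 and Opcml, between -5.82 and -4.41.

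Skeletal genes rose in 8-week osteoblasts. Of the 17 osteoblast matrix genes 13 rose, also when adjusted over the list alone (list median 1.23, adjusted p = 3.45e-09 by camera; adjusted p = 0.205 with an estimated correlation). Among them were Ifitm5 at 3.51 ± 0.233, the collagen gene Col22a1 at 2.44 ± 0.194 and Alpl at 3.29 ± 0.308. Of 14 osteogenic transcription factors 9 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.000152 by camera; adjusted p = 0.216 with an estimated correlation). Among them was Vdr at 3.90 ± 0.208. Of 14 osteocyte genes 7 rose and 1 fell, and 7 rose and 3 fell when adjusted over the list alone (adjusted p = 0.00666 by camera; adjusted p = 0.211 with an estimated correlation). Dmp1, a matrix gene of mineralising osteocytes, rose by 4.46 ± 0.402 and Ptprz1 by 4.31 ± 0.347. All 19 chondrocyte genes rose, also when adjusted over the list alone (list median 2.94, adjusted p = 6.26e-16 by camera; adjusted p = 0.211 with an estimated correlation). Among them were Col10a1 at 5.12 ± 0.297 and Hapln1 at 4.14 ± 0.295. Here too, which cells inside the osteoblast gate express the chondrocyte genes was not tested. Of 9 tendon and ligament genes 6 rose, and 8 when adjusted over the list alone (adjusted p = 9.84e-05 by camera; adjusted p = 0.276 with an estimated correlation), with Scx at 1.99 ± 0.261. Of 29 genes of collagen folding 9 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.00214 by camera; adjusted p = 0.211 with an estimated correlation). Among them were P3h1 at 0.80 ± 0.081 and Fkbp10 at 0.69 ± 0.076.

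Leukocyte genes were higher in 8-week osteoblasts. Of 12 granulocyte genes 5 rose, and 6 when adjusted over the list alone (list median 1.68, adjusted p = 0.00109 by camera; adjusted p = 0.533 with an estimated correlation). Among them were the granule protein genes Mmp8 at 4.02 ± 0.783 and Ltf at 3.43 ± 0.732. Of 16 macrophage genes 9 rose, also when adjusted over the list alone (list median 1.82, adjusted p = 0.000812 by camera; adjusted p = 0.533 with an estimated correlation). Among them were the lysozyme gene Lyz2 at 2.66 ± 0.457 and Cd14 at 2.04 ± 0.343. These list means were highest in 8-week osteoblast library 1, at 11.019 for granulocytes and 8.879 for macrophages, against 9.25 and 7.3 in library 2 and 9.386 and 7.141 in library 3. Of 11 Schwann and neural genes 6 rose, also when adjusted over the list alone (list median 0.66, adjusted p = 0.000836 by camera; adjusted p = 0.216 with an estimated correlation). Among them was Sox10 at 0.66 ± 0.115. Of 13 pericyte genes 9 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.000288 by camera; adjusted p = 0.25 with an estimated correlation), with Tagln at 2.69 ± 0.144.

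Of 37 cell cycle genes 27 rose in 8-week osteoblasts, and 29 rose and 1 fell when adjusted over the list alone (list median 0.83, adjusted p = 3.18e-12 by camera; adjusted p = 0.216 with an estimated correlation). The spindle checkpoint gene Bub1b rose by 1.08 ± 0.111 and Birc5 by 1.84 ± 0.212. Of 20 glycolysis genes 13 rose and 1 fell, also when adjusted over the list alone (adjusted p = 1.99e-05 by camera; adjusted p = 0.211 with an estimated correlation). Among them were Pfkl at 2.02 ± 0.143 and the lactate transporter gene Slc16a3 at 2.23 ± 0.25. Of 37 Wnt genes 17 rose and 7 fell, and 19 rose and 7 fell when adjusted over the list alone (adjusted p = 0.00404 by camera; adjusted p = 0.249 with an estimated correlation); the ligand gene Wnt4 rose by 1.93 ± 0.149 and Dkk2 differed by -4.12 ± 0.296. Of 25 fibroblast and fascia genes 16 fell and 1 rose, and 17 fell and 3 rose when adjusted over the list alone (adjusted p = 7.55e-06 by camera; adjusted p = 0.211 with an estimated correlation). Among them were Dpp4 at -4.39 ± 0.218 and Clec3b at -4.02 ± 0.233. Of 27 inflammatory genes 13 fell and 3 rose, and 15 fell and 3 rose when adjusted over the list alone (adjusted p = 0.002 by camera; adjusted p = 0.486 with an estimated correlation); Ccl8 differed by -4.33 ± 0.324. Of 26 interferon genes 13 fell, and 17 when adjusted over the list alone (list median -0.53, adjusted p = 3.76e-05 by camera; adjusted p = 0.486 with an estimated correlation). Among them were Ifit2 at -1.46 ± 0.13 and Usp18 at -2.04 ± 0.246. Ly6a, whose protein was used for the sort, so that its difference is no finding, differed by -2.64 ± 0.133. Itgav differed by 0.07 ± 0.059 (adjusted p = 0.4 by limma), and Ptprc rose by 3.22 ± 0.821.

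By limma 4903 genes differed between the populations at 8 weeks, 2296 higher and 2607 lower in osteoblasts, and 1603 by at least 2-fold (976 higher, 627 lower). The share of higher genes was 46.8%, and 31.7% after each array was centred on its median (1889 higher, 4062 lower). Without 8-week osteoblast library 1, one of the libraries left out in turn, 4131 genes passed, of which 3913 were among the 4903 with the same direction. With the leukocyte score as a covariate, an alternative chosen after seeing the data, 2209 passed, of which 2092 were among the 4903. The score was higher in each 8-week osteoblast library than in any progenitor library, so that covariate overlaps with this contrast. The osteocyte list lost its call without genes below the median of all probe sets (adjusted p = 0.315) and with that covariate (adjusted p = 0.083), with which the granulocyte and macrophage lists had an adjusted p of 0.817 and 0.725.

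Across ages, 3449 genes passed in the same direction in both cell type comparisons, 1658 higher and 1791 lower in osteoblasts, where independent calls would share 332 and 399. In opposite directions 9 genes passed. The log2 differences at the 2 ages correlated with r = 0.857 across genes, which are not independent replicates.

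**Figure D2:**
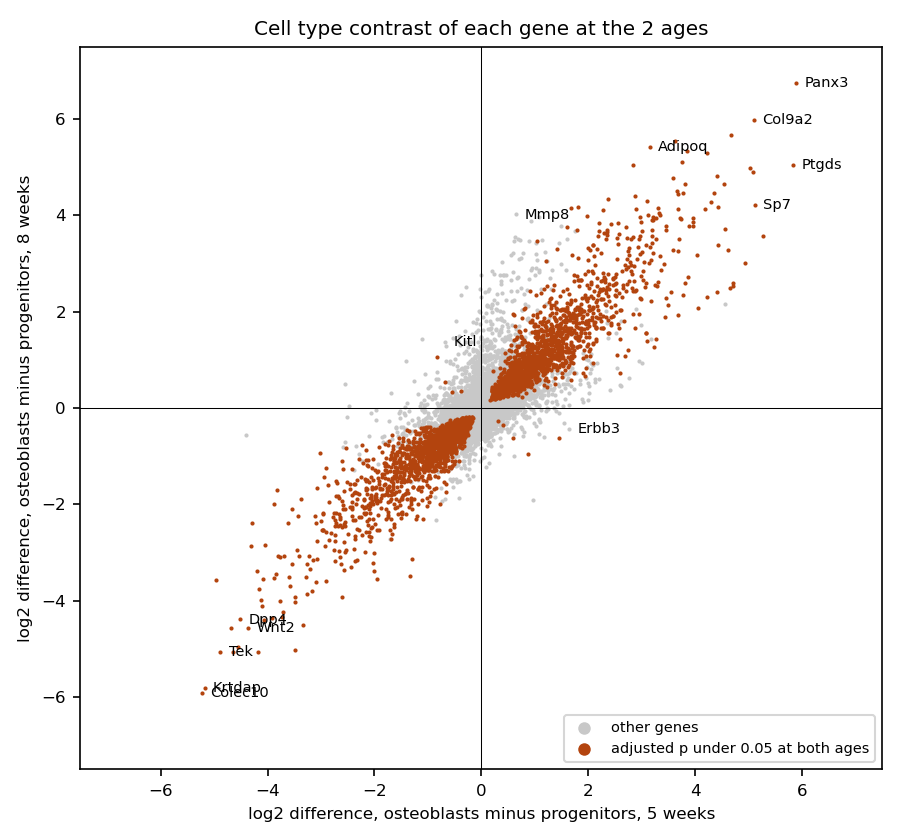
Log2 difference of osteoblasts from progenitors at 5 weeks (horizontal axis) and at 8 weeks (vertical axis); each point is 1 of 16754 genes, coloured where it passed at both ages. The 3449 genes that passed in the same direction lie along the diagonal, with Panx3 at 5.89 and 6.76 and Krtdap at -5.17 and -5.82.

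The comparison of 8-week with 5-week osteoblasts asks what differs with age, and with the labelled sex, within mature cells. Csf1, a macrophage growth factor gene, was 4.38-fold higher at 8 weeks, with a log2 difference of 2.13 ± 0.189 (adjusted p = 0.000844 by limma; chromosome 3, 107741048 to 107760469). Its mean log2 intensity was 8.27 ± 0.28 (SD) at 5 weeks and 10.4 ± 0.4 (SD) at 8 weeks. Kitl, the stem cell factor gene, rose by 2.01 ± 0.277 (4.02-fold; chromosome 10, 100015630 to 100100413), and the lymphoid growth factor gene Il7 by 1.92 ± 0.24. P2rx2, an ATP-gated channel gene, rose by 2.61 ± 0.188 (6.09-fold, adjusted p = 0.00072 by limma; chromosome 5, 110339812 to 110343212), and C2, Serpina3c and H2-Q6 rose by 2.62 ± 0.45, 2.57 ± 0.314 and 2.47 ± 0.386. Fbn2, a fibrillin of developing microfibrils, was 4.83-fold lower at -2.27 ± 0.253 (adjusted p = 0.00175 by limma; chromosome 18, 58008623 to 58209926), and the glial filament gene Gfap was 7.83-fold lower at -2.97 ± 0.46. The other genes with the largest falls were Mogat1, Aldh1a7, Tph2, Spink5, Lrrn3, Srpk3, Agtr2 and Fam84a, between -2.91 and -2.21.

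Genes of the haematopoietic niche and of the interferon response rose in 8-week osteoblasts. Of 18 niche factors and osteoclast regulators 9 rose and 1 fell, and 11 rose and 1 fell when adjusted over the list alone (list median 1.01, adjusted p = 1.03e-08 by camera; adjusted p = 0.151 with an estimated correlation). With Csf1 and Il7 these included Vcam1, an adhesion receptor gene, at 1.80 ± 0.215 and Il34, a second ligand gene of the Csf1 receptor, at 1.70 ± 0.216. Of 23 stromal and skeletal progenitor genes 10 rose and 1 fell, and 12 rose and 3 fell when adjusted over the list alone (list median 0.38, adjusted p = 1.77e-06 by camera; adjusted p = 0.255 with an estimated correlation); the leptin receptor gene Lepr rose by 1.36 ± 0.149 and the transcription factor gene Ebf3 by 1.52 ± 0.174. Of 26 interferon response genes 11 rose, and 14 when adjusted over the list alone (list median 0.68, adjusted p = 3.19e-12 by camera; adjusted p = 0.255 with an estimated correlation). Iigp1, an interferon-induced GTPase gene, rose by 1.92 ± 0.291, and the immunoproteasome genes Psmb9 and Psmb8 by 1.62 ± 0.247 and 1.41 ± 0.22. Of 27 inflammatory genes 4 rose, and 9 when adjusted over the list alone (adjusted p = 0.001 by camera; adjusted p = 0.38 with an estimated correlation), with the interleukin-1 receptor antagonist gene Il1rn at 2.11 ± 0.341. Of 35 BMP and TGF-beta genes 9 rose, and 11 when adjusted over the list alone (adjusted p = 0.0021 by camera; adjusted p = 0.297 with an estimated correlation). Among them were Bmp4 at 1.11 ± 0.172 and Bmp8a at 0.98 ± 0.165.

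Leukocyte markers were higher in the same libraries. The granulocyte list had a median of 1.57 (adjusted p = 1.48e-05 by camera; adjusted p = 0.343 with an estimated correlation), with 7 of 12 genes higher when adjusted over the list alone; Mmp8 was at 3.04 ± 0.783 (adjusted p = 0.0501 by limma). Of 16 macrophage genes 2 rose, and 7 when adjusted over the list alone (list median 1.09, adjusted p = 0.000117 by camera; adjusted p = 0.414 with an estimated correlation): Laptm5 at 2.44 ± 0.583 and Cybb at 2.46 ± 0.6, which lost their calls without 7 and 10 of the 12 libraries in turn. Without 8-week osteoblast library 1 the medians were 0.98 for the granulocyte and 0.47 for the macrophage list, and without 5-week osteoblast library 3 the granulocyte median was 1.04. Myeloid genes were also among the largest rises, with Cd177 at 3.19 ± 0.719, Clec4e at 3.11 ± 0.783, Clec7a at 3.01 ± 0.657, Il1r2 at 2.71 ± 0.595, Hcar2 at 2.68 ± 0.611 and Trem1 at 2.66 ± 0.551. Each of these lost its call without at least 1 library: without 5-week osteoblast library 3 the adjusted p was 0.109, 0.161, 0.0946, 0.0998, 0.1 and 0.0798 in that order. Without 5-week osteoblast library 2 it was 0.0687 for Cd177, 0.0746 for Clec4e, 0.0758 for Clec7a, 0.0563 for Il1r2 and 0.0757 for Hcar2, and without 5-week osteoblast library 1 it was 0.0634 for Hcar2. Clec4e lost its call without 11 of the 12 libraries, and Srpk3 without 8-week osteoblast library 3 (adjusted p = 0.078) or 5-week osteoblast library 3 (adjusted p = 0.0775). Of 14 osteogenic transcription factors 2 rose, also when adjusted over the list alone (adjusted p = 0.00413 by camera; adjusted p = 0.311 with an estimated correlation), with Dlx5 at 0.91 ± 0.2. The osteocyte list (adjusted p = 0.000789 by camera; adjusted p = 0.151 with an estimated correlation) had 1 gene higher, Irx5 at 0.86 ± 0.184, and 4 when adjusted over the list alone. The list of matrix proteases and inhibitors (adjusted p = 0.00159 by camera; adjusted p = 0.255 with an estimated correlation) had 1 gene higher, Mmp23 at 0.75 ± 0.167, and 4 when adjusted over the list alone. Dlx5, Irx5 and Mmp23 lost their calls without 4, 3 and 4 of the 12 libraries in turn, with adjusted p up to 0.0923, 0.0922 and 0.1.

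Cell cycle, Schwann and imprinted genes fell from 5 to 8 weeks in osteoblasts. Of 37 cell cycle genes 6 fell, and 24 when adjusted over the list alone (list median -0.59, adjusted p = 7.34e-13 by camera; adjusted p = 0.255 with an estimated correlation). Among them were Mcm2 at -0.81 ± 0.111 and Mcm3 at -0.55 ± 0.076. Of 11 Schwann and neural genes 4 fell, and 8 when adjusted over the list alone (list median -1.19, adjusted p = 1.86e-07 by camera; adjusted p = 0.151 with an estimated correlation). Sox10 differed by -1.24 ± 0.115 and the neuregulin receptor gene Erbb3 by -1.63 ± 0.218. Of 18 imprinted growth genes 6 fell, and 7 when adjusted over the list alone (list median -0.24, adjusted p = 0.000173 by camera; adjusted p = 0.262 with an estimated correlation). Ppp1r9a, an imprinted neuronal scaffold gene, differed by -1.15 ± 0.092, the zinc finger genes Peg3 and Zim1 by -0.85 ± 0.118 and -1.39 ± 0.247, and Ndn by -0.45 ± 0.077. The erythroid list (adjusted p = 0.0411 by camera; adjusted p = 0.52 with an estimated correlation) had 1 gene lower, also when adjusted over the list alone, Rhd at -1.02 ± 0.231, which lost its call without 4 of the 12 libraries. That list lost its call without 8-week osteoblast library 1 (adjusted p = 0.0654), 8-week osteoblast library 2 (adjusted p = 0.14) or 5-week osteoblast library 1 (adjusted p = 0.497), and after median centring (adjusted p = 0.0806).

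By limma 928 genes differed between the ages in osteoblasts, 544 higher and 384 lower at 8 weeks, and 301 by at least 2-fold. The share of higher genes was 58.6%, and 48.5% after median centring (453 higher, 481 lower). The count was 541 without 8-week osteoblast library 1, of which 485 were among the 928 with the same direction, 447 without 8-week osteoblast library 3, 617 without 5-week osteoblast library 2 and 473 without 5-week osteoblast library 3. It was 358 in a fit of these 2 groups alone and 43 with the leukocyte score as a covariate, all 43 among the 928. Of the 20 genes with the largest changes, P2rx2 alone passed with the covariate. The score was higher in each 8-week osteoblast library than in any other library, so the covariate overlaps with this contrast. With it the median SE of 44 niche and interferon genes rose from 0.208 to 0.29. The lost calls therefore do not measure how much of the change leukocyte RNA accounts for. Over all alternatives Fbn2 stayed between -2.40 and -2.07, while Cd177 ranged from 1.18 to 3.72. With the leukocyte score as a covariate the adjusted p was 0.0811 for the inflammatory list, 0.0811 for the osteocyte list and 0.893 for the granulocyte list.

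The comparison of 8-week with 5-week progenitors asks the same of the less mature cells. Fbn2 was 9.32-fold lower at 8 weeks, with a log2 difference of -3.22 ± 0.253 (adjusted p = 0.00153 by limma), from 10.85 ± 0.47 (SD) to 7.63 ± 0.35 (SD). Alx1, a homeobox gene of craniofacial mesenchyme, was 5.19-fold lower at -2.38 ± 0.262 (chromosome 10, 103007846 to 103029054), and the imprinted gene Zim1 was 5.01-fold lower at -2.32 ± 0.247 (chromosome 7, 6671269 to 6696450). Akr1c14, a hydroxysteroid dehydrogenase gene, was 4.06-fold lower at -2.02 ± 0.184 (adjusted p = 0.00153 by limma; chromosome 13, 4049011 to 4090422). Lgr6 rose 4.43-fold, by 2.15 ± 0.309 (adjusted p = 0.0198 by limma), H2-Ab1, a class II antigen presentation gene, by 2.36 ± 0.345, and the bone matrix gene Spp1 by 1.97 ± 0.343. The other largest rises were Hoxc13, Mmp13, Slc6a4, Tnn, Eif2s3y, Aldh3a1 and Vipr2, between 1.31 and 2.05. The other largest falls were Col25a1, Spock3, Stc1, Mia, Agtr2 and Esrrg, between -2.96 and -1.95. Of the 3 probe sets of Col25a1 and the 2 of Esrrg, 1 each pointed the other way.

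Imprinted and cell cycle genes fell from 5 to 8 weeks in progenitors, and Y-linked genes rose. Of 18 imprinted growth genes 5 fell, and 9 when adjusted over the list alone (list median -0.30, adjusted p = 4.34e-09 by camera; adjusted p = 0.263 with an estimated correlation), with Peg3 at -1.32 ± 0.118 (adjusted p = 0.00153 by limma; chromosome 7, 6703892 to 6730431). Of 37 cell cycle genes 5 fell, and 18 fell and 1 rose when adjusted over the list alone (list median -0.51, adjusted p = 2.49e-11 by camera; adjusted p = 0.335 with an estimated correlation). Among them were Cenpa at -0.91 ± 0.169 and Bub1b at -0.59 ± 0.111; each lost its call without 11 of the 12 libraries. Of 17 genes of the IGF axis 3 fell, and 4 when adjusted over the list alone (adjusted p = 0.0238 by camera; adjusted p = 0.401 with an estimated correlation). These were Stc1 at -2.91 ± 0.414, which encodes an inhibitor of the protease that Pappa encodes, Pappa itself at -1.32 ± 0.198, and the growth factor gene Igf2 at -0.78 ± 0.142. The collagen folding list (list median -0.07, adjusted p = 0.00431 by camera; adjusted p = 0.284 with an estimated correlation) had 1 gene lower, also when adjusted over the list alone, Kdelr3 at -0.35 ± 0.065, which encodes a retrieval receptor of the endoplasmic reticulum. The skeletal muscle list had a median of -0.23 (adjusted p = 0.0122 by camera; adjusted p = 0.478 with an estimated correlation). The Schwann list had a median of -0.37 (adjusted p = 0.0398 by camera; adjusted p = 0.478 with an estimated correlation), with 2 genes lower when adjusted over the list alone and Gfap at -2.17 ± 0.46 (adjusted p = 0.0624 by limma). The immediate early list had a median of 0.18 (adjusted p = 2.17e-06 by camera; adjusted p = 0.478 with an estimated correlation), with 5 of 29 genes higher when adjusted over the list alone and Ier2 at 0.64 ± 0.141 (adjusted p = 0.0692 by limma). The osteogenic transcription factors had a median of 0.20 (adjusted p = 0.00526 by camera; adjusted p = 0.478 with an estimated correlation), with 3 of 14 higher when adjusted over the list alone and Dlx5 at 0.92 ± 0.2 (adjusted p = 0.066 by limma). The BMP and TGF-beta list (adjusted p = 0.0195 by camera; adjusted p = 0.478 with an estimated correlation) had 1 gene higher, Ltbp2, which encodes a TGF-beta binding protein, at 1.10 ± 0.095, and 2 when adjusted over the list alone.

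By limma 158 genes differed between the ages in progenitors, 73 higher and 85 lower at 8 weeks, and 49 by at least 2-fold. The share of higher genes was 46.2%, and 55.3% after median centring (78 higher, 63 lower). The count was 53, 35 and 18 without 8-week progenitor libraries 1, 2 and 3, 104 and 97 without 8-week osteoblast libraries 1 and 3, 56 and 102 without 5-week progenitor libraries 1 and 3, and 66 and 96 without 5-week osteoblast libraries 1 and 2. Of the 20 genes with the largest changes, Fbn2, Akr1c14, Zim1 and Alx1 passed without each library in turn, and the other 16 lost their call without at least 1. Without 8-week progenitor library 3 the adjusted p was 0.0555 for Spock3, 0.0658 for Stc1 and 0.0592 for Mia, and without 8-week progenitor library 2 it was 0.0607 for Stc1, 0.0578 for Mia and 0.0628 for Lgr6. The remaining 12 lost their calls without 4 to 10 of the libraries, with an adjusted p up to 0.172 for Hoxc13 without 8-week progenitor library 3. Lists lost their calls as well. Without 8-week progenitor library 1 the adjusted p was 0.0635 for skeletal muscle, 0.0882 for Schwann genes and 0.0886 for the IGF axis, without 8-week progenitor library 2 it was 0.0536 for Schwann genes, and without 8-week progenitor library 3 it was 0.0748 for the BMP and TGF-beta list. Without 5-week progenitor library 1 it was 0.0804 for skeletal muscle and 0.102 for BMP and TGF-beta, without 5-week progenitor library 2 it was 0.326 for Schwann genes, and without 5-week progenitor library 3 it was 0.0812 for BMP and TGF-beta. The Schwann list also lost its call without genes below the median of all probe sets (adjusted p = 0.29). The count was 13 in a fit of these 2 groups alone, 57 with the replicate number as a block, 260 without genes below the median of all probe sets, and 68 with the leukocyte score as a covariate, of which 64 were among the 158. The fit of these 2 groups alone ended 16 of the 20 calls, that of Alx1 among them. The covariate ended those of Hoxc13, Mmp13, Spp1, Tnn, Aldh3a1, Agtr2 and Esrrg. The block ended those of Hoxc13, Mmp13, Spp1, Aldh3a1 and Vipr2.

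Across cell types, 64 genes passed in the same direction with age in both, 31 higher and 33 lower at 8 weeks, where independent calls would share 2.37 and 1.95. Fbn2, Agtr2, Peg3, Zim1, Ppp1r9a and Igf2 were among those lower in both. The log2 differences correlated with r = 0.384 across genes, which are not independent replicates, and 3 genes passed in opposite directions.

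**Figure D3:**
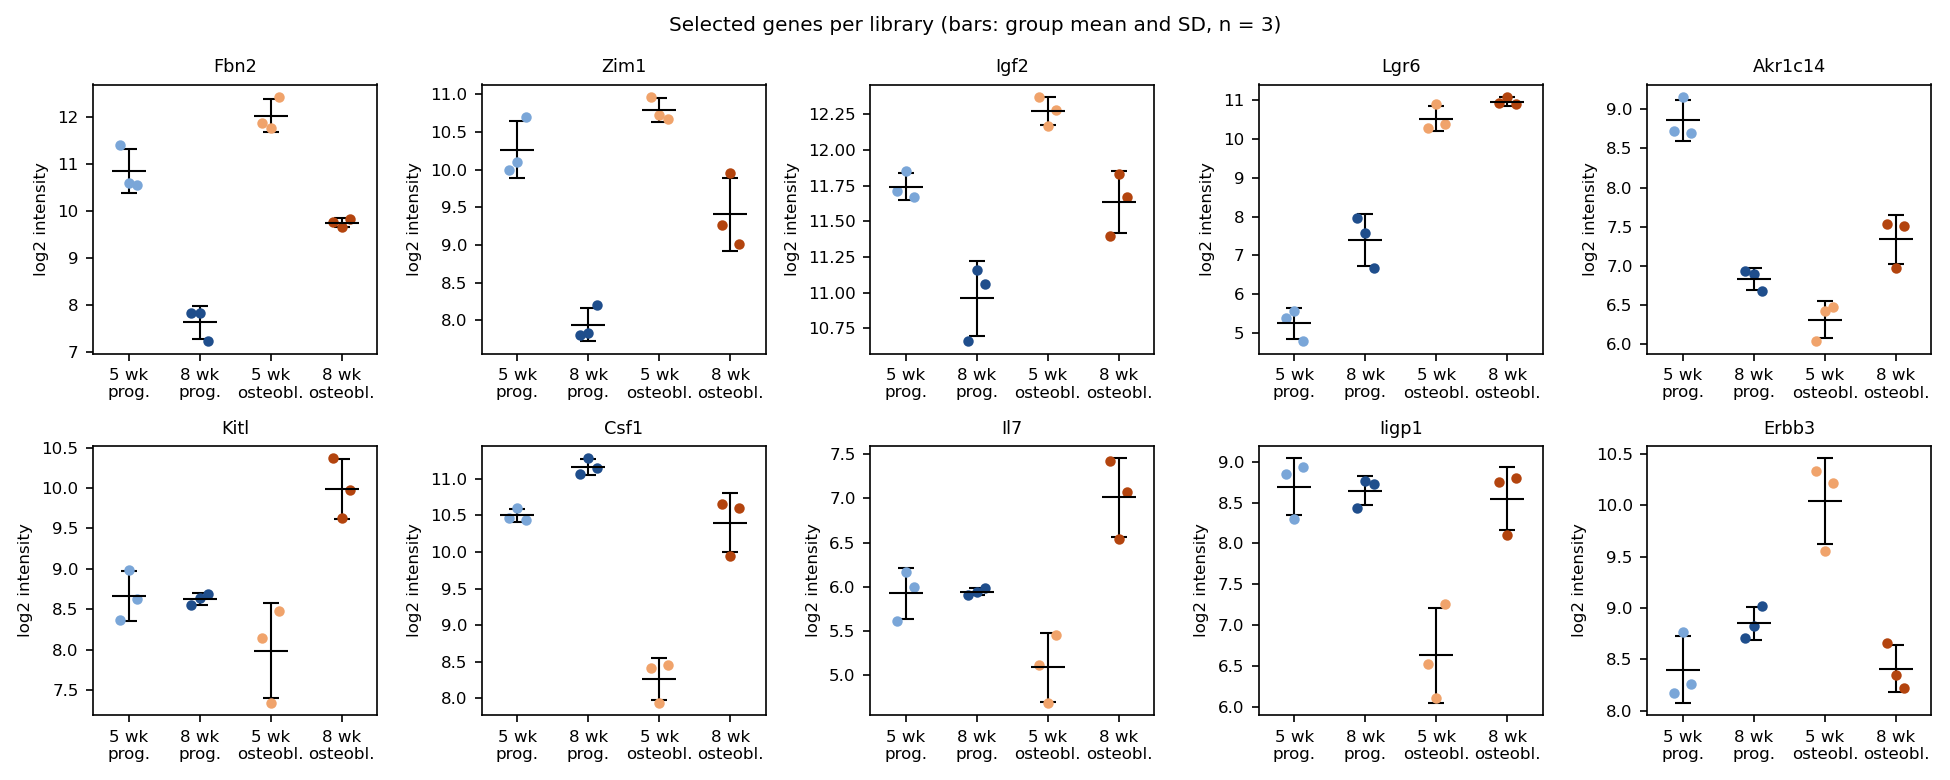
Log2 intensity of Fbn2, Zim1, Igf2, Lgr6, Akr1c14, Kitl, Csf1, Il7, Iigp1 and Erbb3 in each of the 12 libraries, grouped by age and cell type; points are libraries, and bars give the group mean with its SD. Fbn2 falls from a mean of 10.85 to 7.63 in progenitors and from 12.03 to 9.75 in osteoblasts.

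The difference between the cell type contrasts at 8 and at 5 weeks asks which genes separate the populations differently at the older age. Akr1c14 had a difference of 3.04 ± 0.26 (adjusted p = 0.00413 by limma), with means of 8.86 ± 0.26 (SD) in 5-week progenitors, 6.31 ± 0.24 (SD) in 5-week osteoblasts, 6.84 ± 0.14 (SD) in 8-week progenitors and 7.34 ± 0.31 (SD) in 8-week osteoblasts. Pappa, a protease gene that releases IGF from its binding proteins, had a difference of 2.32 ± 0.281 (adjusted p = 0.028 by limma; chromosome 4, 65124174 to 65357509), and Erbb3 of -2.08 ± 0.308 (adjusted p = 0.0387 by limma; chromosome 10, 128567523 to 128589652). The complement gene C6, Adgrf5 and Ccdc68 had differences of 2.10 ± 0.303, 1.96 ± 0.27 and 1.89 ± 0.249, and Shtn1, Acsbg1, Dusp15 and Cyp2j6 of -2.07 ± 0.248, -2.03 ± 0.329, -1.97 ± 0.298 and -0.98 ± 0.151. Among the lists, the interferon response had a median difference of 0.53 (adjusted p = 6.65e-12 by camera; adjusted p = 0.339 with an estimated correlation), with 0 of 26 genes past the limma test over all genes, 13 at an unadjusted p under 0.05, and 7 higher when adjusted over the list alone. The niche factors had a median of 0.71 (adjusted p = 4.89e-06 by camera; adjusted p = 0.339 with an estimated correlation), with 0 of 18 past the limma test over all genes, 12 at an unadjusted p under 0.05, and 8 higher and 2 lower when adjusted over the list alone. The Schwann list had a median of -0.61 (adjusted p = 0.00208 by camera; adjusted p = 0.339 with an estimated correlation), with 2 genes lower, Sox10 at -1.28 ± 0.163 and Erbb3, and 3 when adjusted over the list alone. It lost its call without genes below the median of all probe sets (adjusted p = 0.0914).

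By limma 29 genes passed in this contrast, 18 higher and 11 lower, and 23 by at least 2-fold. The share of higher genes was 62.1%, and 46.9% after median centring (15 higher, 17 lower). The count was 2, 5 and 2 without 8-week progenitor libraries 1, 2 and 3, 2, 55 and 2 without 8-week osteoblast libraries 1, 2 and 3, 1 and 17 without 5-week progenitor libraries 1 and 3, and 59 and 16 without 5-week osteoblast libraries 2 and 3. Of the 10 named genes, Akr1c14 passed without each library in turn, and the other 9 lost their call without 4 to 10 of the 12, as without 5-week progenitor library 1, where the adjusted p was 0.0665 for Pappa, 0.0867 for Erbb3 and 0.0665 for Shtn1. With the replicate number as a block 0 genes passed by limma, with 1694 at an unadjusted p under 0.05.

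Sex-linked genes were examined because the ages carry different sex labels. The X inactivation RNA Xist was not measured, so it could not be used to check the labels. Of 7 Y-linked genes 3 rose from 5 to 8 weeks in progenitors, and 4 when adjusted over the list alone (list median 1.15, adjusted p = 1.71e-05 by camera; adjusted p = 0.263 with an estimated correlation), and 3 rose in osteoblasts, also when adjusted over the list alone (list median 0.58, adjusted p = 0.00407 by camera; adjusted p = 0.255 with an estimated correlation). Ddx3y, an RNA helicase gene, rose by 1.15 ± 0.097 in progenitors and 0.58 ± 0.097 in osteoblasts (adjusted p = 0.00153 and 0.00814 by limma; chromosome Y, 1260771 to 1286629). Uty, a histone demethylase gene, rose by 1.15 ± 0.135 and 0.90 ± 0.135. In the 5-week libraries, labelled female, Ddx3y was at 9.41 to 10.25 and Eif2s3y at 9.07 to 10.19 in log2 intensity, against 10.54 to 10.83 and 10.73 to 11.19 in the 8-week libraries, labelled male. Ddx3y, Eif2s3y and Kdm5d stood at or above the 44.6th percentile of all genes in each 5-week library. The list of X-linked genes that escape inactivation was lower at 8 weeks in osteoblasts (list median -0.18, adjusted p = 0.0411 by camera; adjusted p = 0.255 with an estimated correlation) and in progenitors (list median -0.27, adjusted p = 0.0238 by camera; adjusted p = 0.335 with an estimated correlation). Of its 3 genes Kdm6a, the X-linked homologue of Uty, fell in osteoblasts at -0.72 ± 0.138, also when adjusted over the list alone, and was at -0.65 ± 0.138 in progenitors (adjusted p = 0.0616 by limma), where 2 of the 3 genes were lower when adjusted over the list alone. The osteoblast call of this list was lost without 8-week osteoblast library 1 (adjusted p = 0.0518), 8-week osteoblast library 3 (adjusted p = 0.0527) or 5-week osteoblast library 1 (adjusted p = 0.0705), and the progenitor call without 8-week progenitor library 1 (adjusted p = 0.0635) or 5-week progenitor library 2 (adjusted p = 0.0895).

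The authors' deposited tables hold 10282 genes for the cell types at 5 weeks, of which 5797 had a q-value under 0.05 (2695 higher and 3102 lower in osteoblasts). At 8 weeks the authors' deposited table had 5268 of 10324 (2454 higher, 2814 lower). The authors' deposited table for age in osteoblasts had 1268 of 10192 (695 higher, 573 lower), and the authors' deposited table for age in progenitors 291 of 9912 (159 higher, 132 lower). Of these genes 5750, 5234, 1261 and 288 in the authors' deposited tables were matched by symbol, and of the matched ones 69.9%, 72.6%, 55.6% and 37.5% also passed in the same direction here, in that order. The thresholds differ, since the q-value method is not stated and more genes were tested here. A Benjamini-Hochberg adjustment of the p-values in the authors' deposited tables left 4206, 4062, 792 and 172 genes under 0.05. Over all genes matched by symbol, whatever their q-value, the log2 differences in the authors' deposited tables correlated with those here. The r was 0.985, 0.985, 0.967 and 0.912 across genes, which are not independent replicates.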

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

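The tests of fewer Schwann cells and of the 3 explanations for Y-linked transcripts, the leukocyte ratios of the niche and interferon genes apart, and the fits with a leukocyte score, were chosen after the results were seen. All results here were singled out because the cell type contrast differed between ages in its own test, or because their markers moved with a group. By limma 29 genes differed in that test. The count was 2, 5 and 2 without 8-week progenitor libraries 1, 2 and 3, 2, 55 and 2 without 8-week osteoblast libraries 1, 2 and 3, 1 and 17 without 5-week progenitor libraries 1 and 3, and 59 and 16 without 5-week osteoblast libraries 2 and 3. Of 100 relabellings of age within each cell type, 6 gave as many genes, the real one included, and the highest other gave 187. The 5 others gave 32, 83, 119, 131 and 187 genes; each kept the true ages of the osteoblasts and mixed those of the progenitors, so that a true age difference remained in them and the share does not say how often chance gives 29 genes. For the pairwise comparisons the 10 splits are too few for a share under 0.05. In each, 1 split gave as many genes, the real one itself. The real and highest other values were 4981 and 1 for cell types at 5 weeks, 4903 and 0 for cell types at 8 weeks, 928 and 1 for age in osteoblasts, and 158 and 3 for age in progenitors.

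The differences of the contrast were 3.04 for Akr1c14, 2.32 for Pappa, 2.10 for C6, 1.96 for Adgrf5 and 1.89 for Ccdc68. They were -2.08 for Erbb3, -2.07 for Shtn1, -2.03 for Acsbg1, -1.97 for Dusp15 and -0.98 for Cyp2j6. Among gene lists the median differences were 1.26 for granulocytes (adjusted p = 0.00146 by camera; adjusted p = 0.678 with an estimated correlation), 0.82 for macrophages (adjusted p = 0.00253; 0.805 with an estimated correlation) and 0.23 for stromal progenitors (adjusted p = 8.61e-06; 0.339 with an estimated correlation). They were 0.42 for adipogenic genes (adjusted p = 0.00222; 0.359 with an estimated correlation), 0.31 for osteocytes (adjusted p = 0.0212; 0.339 with an estimated correlation), 0.19 for matrix proteases (adjusted p = 0.0146; 0.382 with an estimated correlation) and 0.19 for the IGF axis (adjusted p = 0.0019; 0.339 with an estimated correlation). The remaining values were 0.71 for niche factors, 0.53 for the interferon response, -0.61 for Schwann genes and -0.15 for immediate early genes (adjusted p = 0.0169; 0.842 with an estimated correlation). By limma over all genes 1 gene of the IGF axis passed, and 0 stromal progenitor, 0 adipogenic and 0 matrix protease genes did, with 11, 5 and 5 at an unadjusted p under 0.05. When adjusted over the list alone 9, 5 and 3 of these were higher. Of the osteocyte, granulocyte, macrophage and immediate early genes 0 passed, with 3, 2, 2 and 3 at an unadjusted p under 0.05. When adjusted over the list alone 0 of these passed. Without 8-week osteoblast library 1 the adjusted p was 0.094 for macrophages, 0.0898 for osteocytes and 0.0635 for immediate early genes. Without 5-week progenitor library 2 it was 0.0929 for osteocytes and 0.119 for matrix proteases, without 5-week osteoblast library 2 it was 0.0607 for osteocytes, matrix proteases and immediate early genes, and without 8-week progenitor library 1 it was 0.0596 for matrix proteases. For immediate early genes it was 0.14, 0.0543, 0.105 and 0.329 without 8-week progenitor library 2, 8-week progenitor library 3, 8-week osteoblast library 3 and 5-week progenitor library 3. Without genes below the median of all probe sets the adjusted p was 0.4 for osteocytes, 0.126 for macrophages and 0.0914 for Schwann genes, and with the leukocyte score as a covariate it was 0.326 for osteocytes and 0.755 for granulocytes.

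Schwann and myelin genes were higher in osteoblast than in progenitor libraries and lower at 8 than at 5 weeks, with Sox10 at 6.89 in 5-week and 5.66 in 8-week osteoblasts against 4.95 and 4.99 in progenitors, which are below the lower quartile of the libraries, although at 8 weeks 6 of the 11 genes passed. Schwann cells inside the osteoblast gate remain open, and the labels do not give that gate. A second list held 21 Schwann genes, 9 of which progenitors express above the median and 1 of which another list holds. This second list had a median of 1.178 at 5 weeks and 0.362 at 8 weeks, where 4 rose and 3 fell. Of the 11 fixed Schwann genes progenitors express 2 above the median and other lists hold 0. Fewer Schwann cells alone at 8 weeks could account for the fall if Schwann genes fell alike: for the 21 genes of the 2 lists that were at least 2-fold higher in 5-week osteoblasts than in progenitors, a choice that favours a fall and of which 8 passed as lower, the SD of the changes divided by 2 times their median SE was 1.144 (0.524 to 1.677 over 2000 resamplings of the genes), which leaves it open. Expression of these genes by the osteoblasts themselves, or a difference by age or sex, was not tested and also stays open.

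Niche factor and interferon genes were higher in 8-week osteoblasts beside granulocyte genes, whose most abundant members S100a8 and S100a9 were at 12.96 and 12.88 in 8-week and 11.78 and 12.16 in 5-week osteoblasts, and the macrophage gene Lyz2, at 12.1 and 10.75. Of 12 granulocyte genes 7 and of 16 macrophage genes 4 are above the median in progenitors, and 1 of the former is in another list. The gate on Lin is not given, so whether it removed leukocytes is not known. Ptprc was at 10.99, 8.33 and 7.62 in the 8-week osteoblast libraries, against 4.62 to 6.99 in the 5-week osteoblast libraries. Leukocyte RNA as the whole source stays open for the 44 genes. With the leukocyte score as a covariate their median change was 0.608 against 0.733 without it, a ratio of 0.83 (0.797 without 5-week progenitor library 2 to 0.948 without 8-week osteoblast library 1). The granulocyte median went from 1.571 to -0.033 by construction. The covariate rests on the spread of the score within groups, where 8-week osteoblast library 1 stood apart at 9.8, against 8.14 and 8.1 in libraries 2 and 3. With the covariate the median SE of the 44 genes rose from 0.208 to 0.29, so the ratio does not decide. By themselves the interferon genes had a ratio of 0.893 (0.814 without 8-week osteoblast library 3 to 1.017 without 8-week osteoblast library 1). The niche factors went from 1.01 to 0.694, a ratio of 0.687 (0.592 without 5-week osteoblast library 2 to 0.843 without 8-week osteoblast library 1). Leukocyte RNA stays open for both sets. Marrow reticular stromal cells inside the 8-week osteoblast gate are a candidate source: a second list of 16 of their genes had a median change of 0.7, with 14 above 0 and 11 called higher, against 0.082 in progenitors, but progenitors express 15 of the 16 above the median, other lists hold 4, and Cxcl12, at 11.97 and 12.92, is near the top of the intensity range, so expression by osteoblasts, age or sex, untested, stay open.

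Y-linked transcripts were present in the 5-week libraries labelled female. Signal from the X homologue alone is argued against for Kdm5d only, which ranged over 1.41 and its homologue Kdm5c over 0.44 in those libraries, a ratio of 3.18. Within 5-week progenitors Kdm5d was at 7.29 to 8.7 and Kdm5c at 9.93 to 10.14, so the 2 probe sets differ in brightness. For Ddx3y the ratio was 3.06, but most of its range lay between cell types, at 9.41 to 9.6 in progenitors and 10 to 10.25 in osteoblasts. The ratio was 1 for Uty, which is near the lower quartile there. For Ddx3y and Uty this explanation stays open. A labelling error with 5-week animals that are all male stays open: the smaller median change of 4 Y-linked genes between ages was 0.801, and the X-linked Kdm6a was at 8.27 to 8.59 in the 5-week and 7.4 to 7.91 in the 8-week libraries, both the way the labels say, but age and any array run go with them. Male cells in a share that differs between 5-week libraries may account for the signal: Eif2s3y and Kdm5d had r = 0.862 (exact permutation p = 0.036, adjusted over 2 relations 0.036) and rho = 0.714 (exact permutation p = 0.14) over the 6 libraries, and r = 0.753 without the 2 farthest. The 8-week libraries had r = 0.859 (exact permutation p = 0.018) and rho = 0.886 (exact permutation p = 0.033), so a correlation of this size is not confined to 5 weeks. There Kdm5d was at 9.28 to 9.56 in progenitors and 8.88 to 9.21 in osteoblasts. The permutations treat the 6 libraries of an age as exchangeable although they hold 2 cell types. The p-values therefore do not measure a relation within a cell type, and the share stays open.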

How the results depend on the processing

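The leukocyte score as a covariate was the alternative chosen after seeing the data; the others were planned, and 2 of the libraries left out were singled out later. No alternative run for the 90 named values reversed any of them; all probe sets and the 2-fold minimum were run for counts alone, and 1 probe set each of Col25a1 and Esrrg pointed the other way. Of the alternative values 1917 kept direction and side of the threshold and 260 no longer passed. In the alternatives run for lists that passed, 1115 kept both, 141 no longer passed and 2 reversed, namely the macrophage list with the covariate, for age in osteoblasts (adjusted p = 0.958) and for the difference between ages (adjusted p = 0.758), which the covariate's construction from that list causes. Over libraries left out in turn the counts of genes were 4056 to 4890 and 3976 to 4910 for cell types at 5 and 8 weeks, 447 to 937 for age in osteoblasts, 18 to 163 for age in progenitors and 1 to 59 for the difference between ages, with fewer samples in each fit. Those of lists were 14 to 18, 16 to 18, 14 to 17, 9 to 12 and 8 to 15 in that order. With the replicate number as a block, 57 genes passed for age in progenitors, 26 for age in both cell types and 0 by limma for the difference between ages, with 1694 at an unadjusted p under 0.05. The block also ended the calls of 5 named genes for age in progenitors, of all 10 for the difference between ages and of the osteocyte list there (adjusted p = 0.0505), and no other named or list call. The labels do not call libraries of the same number pairs, and they were not treated as such; their residuals correlated across genes with r from -0.079 to 0.215, higher than with any other number except for numbers 2 and 3 between cell types at 8 weeks. The 2 groups alone, with fewer samples, gave 358 genes for age in osteoblasts and 13 in progenitors. Without genes below the median, where fewer genes are tested, 260 passed for age in progenitors and 6 for the difference between ages, and limma-trend gave 65 for the latter; the cause was not tested. The 2-fold minimum, stricter by construction, left 1640, 1603, 301 and 49 genes, and 1169 and 14 shared ones. With the covariate 2209 genes passed for cell types at 8 weeks, 43 and 68 for age in osteoblasts and progenitors and 2 for the difference between ages; the score itself is higher in each 8-week osteoblast library than in any other, and the cause was not tested. Camera with an estimated correlation called 0 lists in each of the 5 contrasts, with 9, 9, 7, 5 and 5 at an unadjusted p under 0.05; the cause was not tested. Fry called 22, 20, 12, 7 and 0, with 8 at an unadjusted p in the last, and 15, 16, 11, 6 and 0 of its lists were also called by camera. Lists that camera called and fry did not were, for age in osteoblasts, the granulocyte, macrophage, inflammatory, osteogenic factor and erythroid lists. For age in progenitors they were the osteogenic factor, immediate early, skeletal muscle, Schwann, and BMP and TGF-beta lists. For cell types at 5 weeks it was the immediate early list (adjusted p = 0.0599 by fry). For the difference between ages it was all 11 lists that camera called, among them the interferon list (adjusted p = 0.125 by fry) and the niche factors (adjusted p = 0.103 by fry). Of list members that passed, 294 of 347, 274 of 330, 39 of 97, 5 of 25 and 0 of 3 passed without each library in turn. A block for slide or scan date was not run.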

Other observations

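No tests here were chosen after the results were seen, but all genes named were chosen after their values were seen. Type I collagen genes were near the top of the intensity range, 13.7, where arrays compress differences, so their values do not say whether the populations differ: Col1a1 had a mean of 12.943 and differed by -0.02 ± 0.055 (adjusted p = 0.835 by limma) between osteoblasts and progenitors at 5 weeks, and Col1a2 had a mean of 13.076 and differed by 0.02 ± 0.056 (adjusted p = 0.878 by limma). Stromal progenitor genes went both ways at 5 weeks, with Mcam and Grem1, a BMP antagonist gene, higher in osteoblasts at 2.88 ± 0.189 and 2.36 ± 0.236 and Thy1 lower at -2.38 ± 0.172. Of 15 hedgehog genes 4 rose and 5 fell, with the receptor gene Ptch1 and the antagonist gene Hhip higher at 1.12 ± 0.102 and 1.74 ± 0.2. Both lists contained members that rose and members that fell, and neither passed as a whole at 5 weeks by camera (adjusted p = 0.181 and 0.819 by camera). Fry called the stromal list lower in osteoblasts (adjusted p = 0.026 by fry) and did not call the hedgehog list (adjusted p = 0.785 by fry). When adjusted over the list alone, 13 of 23 stromal genes fell and 6 rose.

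The homeobox and T-box genes that follow were picked for their values; such genes were not tested as a list, and those that did not change were not counted. Alx1 was lower at 8 weeks in both cell types, at -1.58 ± 0.262 in osteoblasts (adjusted p = 0.00782 by limma) and -2.38 ± 0.262 in progenitors, and so was En1 at -1.10 ± 0.136 and -0.83 ± 0.136 (adjusted p = 0.00268 and 0.0294 by limma). Hoxc10 was higher at 0.54 ± 0.106 and 0.69 ± 0.106 (adjusted p = 0.0173 and 0.0261 by limma). Between cell types at 5 weeks, Hoxa11, Pax9 and Tbx15 were lower in osteoblasts at -1.28 ± 0.274, -1.80 ± 0.135 and -1.23 ± 0.175 (adjusted p = 0.00486, 7.24e-06 and 0.000376 by limma). The labels do not say which bones were digested.

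In none of the 5 contrasts did camera call 10 of the lists. Their lowest adjusted p was 0.446 for B lymphoid, 0.178 for T and NK, 0.651 for endothelial, 0.337 for mast cell, 0.193 for megakaryocyte, 0.073 for osteoclast, 0.286 for Notch, 0.418 for hedgehog, 0.193 for oxidative phosphorylation and 0.0593 for steroid receptor genes. Fry called some of them. For steroid receptor genes its adjusted p was 0.00588 and 0.0196 for cell types at 5 and 8 weeks, and 0.0201 and 0.0425 for age in osteoblasts and progenitors. For cell types at 5 weeks it was 0.00302 for T and NK, 0.034 for osteoclast and 0.034 for oxidative phosphorylation genes by fry.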
